A study of Mus musculus with 8 samples.

How the data were processed

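Gene expression was measured on Affymetrix arrays in cells sorted from medulloblastomas of Patched1+/- mice carrying a Sox2-eGFP reporter. Per the labels, the mice received 3 Gy of ionizing radiation at birth and the tumours were taken at over 70 days of age, at the first signs of disease. Cells expressing CD45 (white blood cells) or Ter119 (red blood cells) were depleted, and the remaining cells were sorted by eGFP into a Sox2-positive and a Sox2-negative fraction. Each of the 8 arrays held RNA of 1 pool of 3 tumours, with 4 pools per fraction. The p-values measure the spread between such pools, not between single animals.

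The authors deposited 1 value per probe set and array on a log2 scale. Per the submitters' processing notes, the values were made with Affymetrix Expression Console 1.2.0.20 and RMA, which corrects the background, normalizes the arrays to a common distribution and summarises the probes of a set. RMA compresses fold changes of dim genes, and a difference in total RNA per cell between the fractions is removed by the normalization. The log2 scale was read from the values, which ran from 2.51 to 13.6 over all probe sets. The array medians over the genes tested lay between 5.83 and 5.88. The genome build and the version of the probe annotation are not given in the sources used here, so no coordinates are printed.

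The table held 41345 probe sets. The platform annotation named 25335 of them, 23521 with 1 gene symbol and 1814 with several, and 16010 were unnamed here. Of the probe sets with 1 symbol, 23328 were matched by Entrez identifier to a RefSeq gene table of the assembly GRCm38.p6, used for symbols only, and 0 symbols changed. Only probe sets with 1 symbol were used to name genes. For the 1082 genes with several probe sets, the one with the highest mean over all 8 arrays was taken, which left 22180 genes. No filter on dim genes was applied. Levels of different probe sets were compared only to choose 1 per gene, to leave out dimmer genes in an alternative, and as a guide to dim values. The table gives no detection call, so the level of 1394 olfactory and vomeronasal receptor genes, which these cells are not known to use, served as a guide to dim values (quartiles 4.16, 4.95 and 5.80). Of the 85 genes named, 19 had a group mean below 5.80, and 6 had both. A fold against such a level understates the difference if the probe set was at background there.

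The deposited values were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with default settings, group as the only term). Tests were two-sided, and p-values were adjusted by the Benjamini-Hochberg method over all 22180 genes, with a threshold of 0.05. Fold changes are Sox2-positive over Sox2-negative, and log2 differences are Sox2-positive minus Sox2-negative. A total of 30 gene lists, for cell types of the cerebellum and its tumours, pathways and cell states, were written from textbook knowledge before the data were examined. Each list was tested with camera, a competitive test that compares a list with all other genes, at a preset correlation between genes of 0.01, adjusted over the 30 lists. The same lists were tested with an estimated correlation, with ranks and with fry, a rotation test that does not compare a list with other genes. Members were also adjusted over the list alone. Some list members were not analysed here, as they shared a probe set with another gene or were not among the named genes.

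The rule for the genes named was also set before the data were examined. It took 7 genes in every case (Sox2, Ptch1, Gli1, Atoh1, Mki67, Olig2 and Gfap). It added the 12 largest positive and 12 largest negative log2 differences at an adjusted p under 0.05 whose groups did not overlap, leaving out predicted gene models and similar symbols. From each list it took up to 3 members with the largest difference past the test, or the 1 largest where none passed. Together this gave 85 distinct genes.

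The labels number the pools 1 to 4 in both fractions without saying that equal numbers share tumours. Deviations from the group means, over all genes, correlated at 0.164, 0.114, 0.177 and 0.241 between arrays of the same number. The highest correlation between different numbers was 0.161. Of the 8 arrays, 7 correlated best with the array of their own number, and no other of the 24 ways to match the arrays did as well (exact permutation p = 0.0417). The arrays of number 2 correlated less (0.114) than the highest of different numbers (0.161), so the pairing is less sure there. The pairing comes from the data and not from the labels, and the main fit was kept without a block. The replicate number was used as a block in an alternative fit, and its value is printed where it changed a call.

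The procedure was tested on simulated data for this comparison, with 200 of 22180 genes changed in each of 20 simulations at the spread of the real arrays. It recovered 51.3% of genes changed by 0.5 on the log2 scale, 95.2% of those changed by 1 and 99.9% of those changed by 2. False calls made up 3.63% of all calls. The oligodendrocyte progenitor list, with every member shifted by 1 on the log2 scale, was found in 100% of simulations. Smaller shifts and other lists were not simulated. Where no list was shifted, 0.2 lists per simulation were called. The simulated genes varied independently of each other, which real genes do not. The simulation also changed fewer genes than were called in the real comparison (1879, of which 70.3% were higher), and evenly up and down. The recovery rates thus need not hold for the real comparison.

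The alternatives were quantile normalization, median centring, leaving out the dimmer genes (11090 genes kept), a variance trend with robust estimation, array weights, the replicate block, all probe sets tested singly, the mean of a gene's probe sets, and leaving out each array in turn. The number of arrays limits the precision of every value. With 4 arrays against 4, the smallest p an exact permutation test can give is 0.0286, and within 4 pairs it is 0.125. The unnamed probe sets and those of several genes were left out of the comparison and tested apart.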

Results

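Gene expression was compared between Sox2-positive and Sox2-negative cells of medulloblastomas from Patched1+/- mice, a model of the Hedgehog-driven form of this cerebellar tumour. Sox2 is a transcription factor of neural stem and progenitor cells, and the comparison asks how the sorted cells that express it differ from the others. There were 4 arrays of Sox2-positive and 4 of Sox2-negative cells, each a pool of 3 tumours, and 22180 genes were tested. Correlations between arrays were 0.981 to 0.987 within the Sox2-positive group, 0.973 to 0.984 within the Sox2-negative group and 0.942 to 0.968 between the groups. The first principal component held 54.8% of the variance and separated the groups, and the next held 13.3%.

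Sox2-positive cells had higher levels of genes of the oligodendrocyte lineage and of glia. They had lower levels of genes listed for granule neuron progenitors, the cells from which these tumours arise. As groups, with an estimated correlation between genes, only the oligodendrocyte progenitor list of these stayed past the test (adjusted p = 0.0213; granule neuron progenitors 0.072, astrocytes 0.0894, neural stem cells and radial glia 0.0894, mature oligodendrocytes 0.269). Sox2 itself was 3.13-fold higher, at 5.94 ± 0.34 against 4.30 ± 0.29 (mean log2 value ± SD, n = 4 each; log2 difference 1.65, SE 0.17; limma adjusted p = 2.53e-05). Its Sox2-negative level lay below the median of olfactory and vomeronasal receptor genes, not known to be used in these cells (4.95). The fold is thus best read as at least this size. Its Sox2-positive mean lay just above the upper quartile of those genes (5.80), and Sox2-positive pools 1 and 4 (5.67 and 5.68) lay below it. Olig2, a transcription factor of the oligodendrocyte lineage, was 10.9-fold higher, at 9.29 ± 0.38 against 5.84 ± 0.27 (adjusted p = 4.03e-08). Gfap, the intermediate filament of astrocytes, was 1.72-fold higher (adjusted p = 8.06e-05). Atoh1, the transcription factor that specifies granule neuron progenitors, fell by 0.71 on the log2 scale (SE 0.18, adjusted p = 0.0278), and Gli1, a target and effector of Hedgehog signalling, fell by 0.57 (SE 0.16, adjusted p = 0.0461).

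For 2 of the genes named in every case the test was not passed. Mki67, a marker of dividing cells, was at 8.82 ± 0.25 in Sox2-positive and 8.87 ± 0.11 in Sox2-negative cells (log2 difference -0.05, 95% interval -0.31 to 0.21, adjusted p = 0.864). Ptch1, the Hedgehog receptor that is heterozygous in these mice, had a log2 difference of 0.25 (95% interval -0.05 to 0.56, adjusted p = 0.36). The calls of Atoh1 and Gli1 were the least firm of these genes. That of Atoh1 ended without Sox2-positive pool 1, 2 or 3 or Sox2-negative pool 1 or 4 (adjusted p = 0.0543 to 0.0868). That of Gli1 ended without Sox2-positive pool 2, 3 or 4 or Sox2-negative pool 1, 2 or 4, and with array weights (0.0506 to 0.147).

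**Figure D1:**
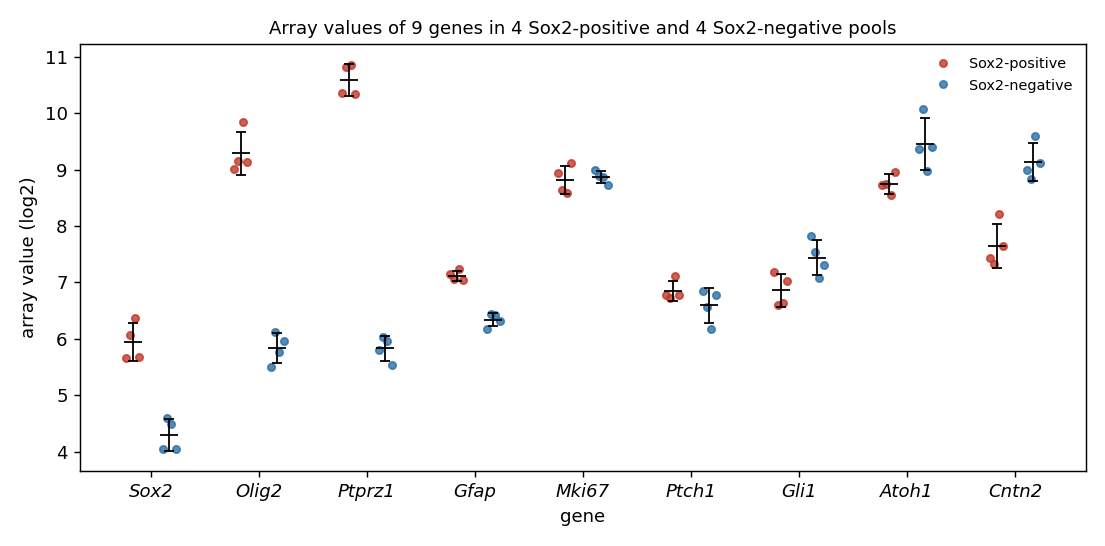
Array values (log2, vertical axis) of the 7 genes named in every case and of Ptprz1 and Cntn2 (horizontal axis) in Sox2-positive (red) and Sox2-negative (blue) cells. Points are single arrays, and bars are the mean and SD of 4 arrays. Olig2 lies between 9.02 and 9.85 in Sox2-positive arrays and between 5.51 and 6.13 in Sox2-negative arrays, while the values of Mki67 overlap.

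In all, 1879 of 22180 genes differed between the fractions (8.47%), 1321 higher and 558 lower in Sox2-positive cells. Of these counts, that of lower genes moved most in proportion over the alternatives, from 309 without Sox2-positive pool 2 to 847 with quantile normalization. At least 2-fold differences were found for 377 genes, 358 higher and 19 lower. At least 4-fold, 81 genes were higher and 0 were lower in the limma test, and 24 genes were higher by at least 8-fold. At an unadjusted p under 0.05, 4454 genes differed. The 4 values of one group all lay above those of the other for 1762 of the 1879 genes, and for 13.7% of all genes, where chance alone gives 2.86%. Higher genes made up 70.3% of the calls, and 60.2% after quantile normalization.

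Serpina3n, a secreted protease inhibitor of reactive astrocytes, had the largest increase, 33.7-fold (log2 difference 5.07, SE 0.34, adjusted p = 4.44e-07). Ptprz1, a receptor phosphatase of radial glia and oligodendrocyte progenitors, was 27.1-fold higher (log2 difference 4.76, SE 0.14, adjusted p = 5.35e-10). Sulf2, which removes sulfate groups from heparan sulfate, was 19.2-fold higher, the gap junction gene Gjc3 was 17.1-fold higher, and the matrix protein gene Tnr was 16.3-fold higher. Olig1, the neighbour of Olig2, was 16.1-fold higher, and the proteoglycan gene Cspg5 was 14.8-fold higher. Tmem176a, the amino acid transporter gene Slc38a3, Gpr37l1 and Scrg1 were between 10.4-fold and 12.5-fold higher. None of these genes overlapped between the groups. The Sox2-negative means of 3 of the 12, Serpina3n (5.14), Scrg1 (5.70) and Olig1 (5.74), lay below the upper quartile of the receptor genes (5.80), so their folds and rank may be understated.

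The largest decreases were smaller than the largest increases. Chrna3, a nicotinic acetylcholine receptor subunit, fell by 1.57 on the log2 scale (SE 0.16, adjusted p = 2.73e-05), which left 0.336 of its level in Sox2-negative cells. The axonal adhesion gene Cntn2 fell by 1.49 (SE 0.19, adjusted p = 0.000169). Reln, which encodes a secreted guide of migrating neurons, fell by 1.38 (SE 0.18, adjusted p = 0.000179). The neuronal transcription factor genes Nhlh1 and Nhlh2 fell by 1.35 and by 1.13. The calcium channel subunit gene Cacna2d1 fell by 1.28 and the vesicular glutamate transporter gene Slc17a6 fell by 1.27. The long noncoding RNA Miat fell by 1.25, the synaptic vesicle gene Sv2b fell by 1.22, and Mab21l1 fell by 1.16. The transcription factor genes Prdm8 and Zic2 fell by 1.15 and by 1.09.

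Of the 30 lists, 16 were shifted in Sox2-positive cells in the camera test with the preset correlation, 12 higher and 4 lower. With an estimated correlation 2 were shifted, those of oligodendrocyte progenitors and of extracellular matrix and adhesion. With fry 11 were shifted, and with ranks 17. The 18 splits of the 8 arrays that put 2 of each fraction on either side gave 0 to 8 shifted lists with the preset correlation. The 16 splits of 3 and 1, which keep part of the real difference, gave 7 to 14. With the estimated correlation no other split gave any (0).

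**Figure D2:**
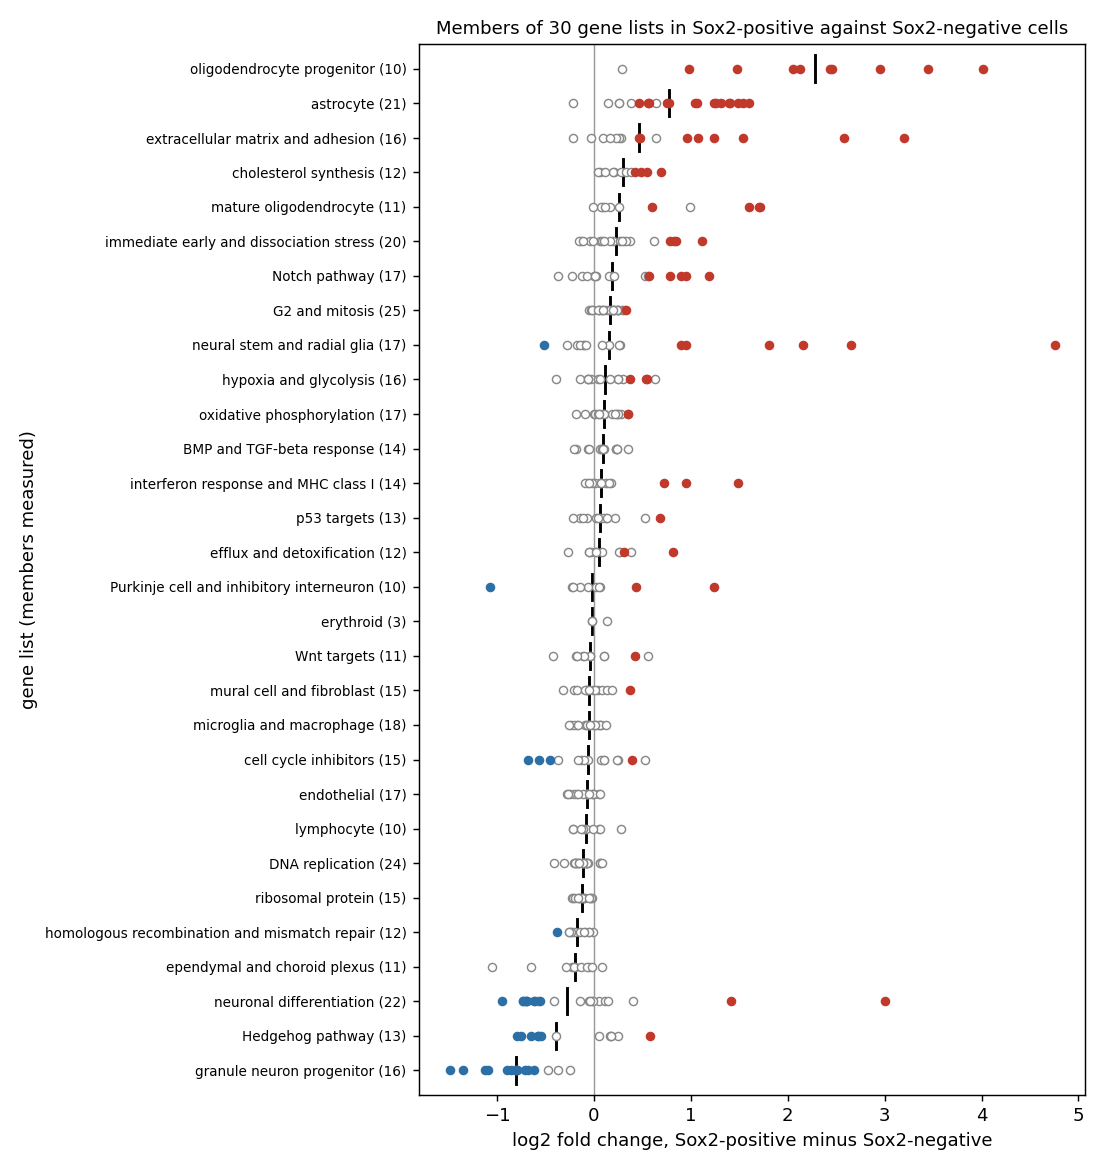
Log2 fold change (Sox2-positive minus Sox2-negative, horizontal axis) of each measured member of 30 gene lists (vertical axis, members measured in parentheses). Filled points passed the limma test over all genes, red higher and blue lower, open points did not, and black bars are list medians. The oligodendrocyte progenitor list has the highest median, 2.28, and the granule neuron progenitor list the lowest, -0.80.

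Genes of oligodendrocyte progenitors rose most as a group. Of 10 measured, 9 were higher and 0 lower, both over all genes and adjusted over the list alone, with a median log2 difference of 2.28 (camera adjusted p = 1.79e-23; adjusted p = 0.0213 with an estimated correlation). Besides Olig1 and Olig2, the receptor gene Gpr17 was 7.73-fold higher (adjusted p = 1.04e-06). Of 11 genes of mature oligodendrocytes, 4 were higher and 0 lower (5 higher adjusted over the list alone), with a median of 0.26 (camera adjusted p = 6.46e-05; adjusted p = 0.269 with an estimated correlation). The myelin lipid enzyme gene Ugt8a was 3.29-fold higher and Cnp 3.27-fold higher. Cldn11 was 3.04-fold higher (adjusted p = 0.0158), a call that ended without Sox2-positive pool 4 (0.0523) and with a variance trend (0.0949).

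Genes of astrocytes were also higher, 15 of 21 with 0 lower (18 higher adjusted over the list alone), at a median log2 difference of 0.78 (camera adjusted p = 1.16e-18; adjusted p = 0.0894 with an estimated correlation). Clu was 3.02-fold, Hepacam 2.91-fold and the lipid carrier gene Apoe 2.79-fold higher. Of 17 genes of neural stem cells and radial glia, 6 were higher and 1 lower (7 and 1 adjusted over the list alone), with a median of 0.16 (camera adjusted p = 0.000503; adjusted p = 0.0894 with an estimated correlation and 0.105 with ranks). Fabp7 was 6.31-fold and the glutamate transporter gene Slc1a3 4.46-fold higher, after Ptprz1. Of 16 genes of extracellular matrix and adhesion, 8 were higher and 0 lower (11 higher adjusted over the list alone), with a median of 0.47 (camera adjusted p = 2.67e-11; adjusted p = 0.0213 with an estimated correlation). Sparcl1 was 9.19-fold higher, and the proteoglycan genes Bcan and Vcan were 5.98-fold and 2.91-fold higher.

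Of 17 genes of the Notch pathway, 5 were higher and 0 lower (7 higher adjusted over the list alone), with a median of 0.19 (camera adjusted p = 0.000434; adjusted p = 0.0577 with an estimated correlation). The receptor gene Notch1 was 1.87-fold higher, and the target genes Hey2 and Hes5 were 2.27-fold and 1.93-fold higher. The other, dimmer probe set of Hes5 had a log2 difference of -0.07, not past the test.

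Genes of the granule neuron progenitor list fell together, 13 of 16 lower and 0 higher, and 16 lower when adjusted over the list alone. Their median log2 difference was -0.80 (camera adjusted p = 1.41e-17; adjusted p = 0.072 with an estimated correlation). Cntn2, Nhlh1 and Nhlh2, described above as axonal or neuronal genes, fell most, further than Atoh1 (log2 difference -0.71). The fall of this list is thus not one of progenitor genes alone. Of 13 Hedgehog pathway genes, 6 were lower and 1 higher (7 and 1 adjusted over the list alone), and the list as a whole did not pass (median -0.39, camera adjusted p = 0.0684; adjusted p = 0.461 with an estimated correlation). Mycn fell by 0.79 on the log2 scale (SE 0.13, adjusted p = 0.00171), Sfrp1 fell by 0.75 and the co-receptor gene Boc fell by 0.65. The list passed without Sox2-negative pool 3 (0.0313) and with the dimmer genes left out (0.0334).

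Of 22 genes of neuronal differentiation, 8 were lower and 2 higher (11 and 3 adjusted over the list alone), with a median of -0.28 (camera adjusted p = 0.019; adjusted p = 0.515 with an estimated correlation), a call lost without Sox2-negative pool 3 (0.0786) and with fry (0.220). Stmn2 fell by 0.94 on the log2 scale (SE 0.20, adjusted p = 0.0101). The higher members were the adhesion genes Cntn1 (8.03-fold) and Ncam1 (2.66-fold), which glial cells also express. Of 10 genes of Purkinje cells and inhibitory interneurons, 2 were higher and 1 lower (the same adjusted over the list alone; median -0.02, mean 0.01, camera adjusted p = 0.978). Car8 was 2.36-fold higher, Lhx1 fell by 1.07, and Gad1 was 1.35-fold higher (adjusted p = 0.0292). The call of Gad1 ended without Sox2-positive pool 2, 3 or 4 or Sox2-negative pool 1 or 3 (0.0691 to 0.0981).

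Few genes of the cell cycle passed the test. Of 25 genes of G2 and mitosis, 1 was higher and 0 lower, and 0 passed when adjusted over the list alone. The list's median was 0.16 (camera adjusted p = 0.00059; adjusted p = 0.467 with an estimated correlation and 0.171 with fry). Ube2c, which marks proteins for breakdown in mitosis, was 1.26-fold higher (adjusted p = 0.0483), a call that 9 of 15 alternatives ended (0.0684 to 0.283), among them leaving out any array except Sox2-positive pool 2. Of 24 DNA replication genes, 0 were higher or lower, also adjusted over the list alone, and the median was -0.11 (camera adjusted p = 0.018; adjusted p = 0.515 with an estimated correlation). That call ended without Sox2-negative pool 2 (0.247) or Sox2-positive pool 1 (0.0538), with array weights (0.0522) and with fry (0.148). Tyms, a nucleotide synthesis gene, had a log2 difference of -0.41 (limma adjusted p = 0.05002; 0.0242 with the replicate block). Without Sox2-negative pool 3 or Sox2-positive pool 4 its adjusted p was 0.0201 and 0.0341, with quantile normalization 0.0271 and with the dimmer genes left out 0.0336. Of 15 cell cycle inhibitor genes, 3 were lower and 1 higher (3 and 2 adjusted over the list alone; median -0.06, camera adjusted p = 0.758). Btg1 fell by 0.67, Btg2 fell by 0.57 and Ccng2 fell by 0.46.

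Of 20 immediate early and dissociation stress genes, 4 were higher and 0 lower, also adjusted over the list alone, with a median of 0.23 (camera adjusted p = 0.000589; adjusted p = 0.245 with an estimated correlation and 0.0511 with fry). Nr4a1 was 2.17-fold and Klf6 1.80-fold higher. Fos was 1.78-fold higher (adjusted p = 0.0184), a call that ended without Sox2-positive pool 3 or Sox2-negative pool 1 or 4 (0.0504 to 0.0606). Of 12 cholesterol synthesis genes, 4 were higher and 0 lower (7 higher adjusted over the list alone), with a median of 0.30 (camera adjusted p = 5.92e-05; adjusted p = 0.299 with an estimated correlation and 0.0581 with fry). Hmgcs1 was 1.62-fold higher. Msmo1 was 1.46-fold higher, a call lost without Sox2-positive pool 2 or 3 or Sox2-negative pool 1, 2 or 4 (0.0605 to 0.0924). Fdps was 1.40-fold higher, a call lost without Sox2-negative pool 1 (0.0538).

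Of 14 interferon response and MHC class I genes, 3 were higher and 0 lower, also adjusted over the list alone (median 0.08, camera adjusted p = 0.0166; adjusted p = 0.299 with an estimated correlation). These were B2m (2.81-fold) and H2-K1 (1.65-fold), the chains of MHC class I, and the antiviral gene Ifitm3 (1.93-fold). Of 16 hypoxia and glycolysis genes, 3 were higher and 0 lower (6 and 1 adjusted over the list alone; median 0.12, camera adjusted p = 0.027; adjusted p = 0.399 with an estimated correlation and 0.104 with fry). The call of the list ended without Sox2-positive pool 3 or 4 or Sox2-negative pool 1, with quantile normalization, with the mean of probe sets and with the dimmer genes left out (0.0503 to 0.176). Pfkp was 1.29-fold higher. The glucose transporter gene Slc2a1 was 1.47-fold higher, a call lost without Sox2-positive pool 3 or 4 or Sox2-negative pool 1 or 3 (0.0566 to 0.0674), and with the mean of its probe sets (0.134), as the dimmer one had a log2 difference of -0.001. Egln3 was 1.45-fold higher, a call lost without Sox2-positive pool 2, 3 or 4 or Sox2-negative pool 1, 2 or 3 (0.0506 to 0.11).

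Of 17 oxidative phosphorylation genes, 1 was higher and 0 lower, and 0 adjusted over the list alone (median 0.11, camera adjusted p = 0.0165; adjusted p = 0.532 with an estimated correlation and 0.246 with fry). The list's call ended without Sox2-positive pool 3 or Sox2-negative pool 1 or 4 and with the dimmer genes left out (0.0514 to 0.151). Sdha was 1.28-fold higher (adjusted p = 0.0485), a call that 10 of 15 alternatives ended (0.0533 to 0.146), among them leaving out any array except Sox2-negative pool 2. Of 12 homologous recombination and mismatch repair genes, 1 was lower and 0 higher (4 lower adjusted over the list alone; median -0.17, camera adjusted p = 0.0105; adjusted p = 0.299 with an estimated correlation). Bard1 fell by 0.38, a call lost without Sox2-positive pool 2 or 3 or Sox2-negative pool 2 or 4 (0.066 to 0.0918).

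Markers of the blood and immune cells that the sort was meant to deplete did not pass the test. Both fractions were sorted after this depletion, so the test compares them and cannot show whether the depletion worked. For microglia and macrophages, 0 of 18 genes passed (median -0.05, camera adjusted p = 0.357; largest difference Ctss, -0.26). For lymphocytes it was 0 of 10 (median -0.08, camera adjusted p = 0.606; Cd79b, 0.28), and for red blood cells 0 of 3 (median -0.02, mean 0.03, camera adjusted p = 0.758; Slc4a1, 0.14). For endothelial cells, 0 of 17 genes passed (median -0.07, camera adjusted p = 0.134; adjusted p = 0.461 with an estimated correlation; Tek, -0.28), and the list passed without Sox2-negative pool 2 (0.0442). No member of these 4 lists passed when adjusted over the list alone. Of 15 genes of mural cells and fibroblasts, 1 was higher, also adjusted over the list alone (median -0.05, camera adjusted p = 0.978). This was Rgs5 (1.29-fold, adjusted p = 0.0174), lost without Sox2-positive pool 4 (0.0571) and with the mean of its probe sets (0.252).

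For ependyma and choroid plexus, 0 of 11 genes passed over all genes or adjusted over the list alone, at a median of -0.19 (camera adjusted p = 0.0535; adjusted p = 0.0215 with the replicate block, 0.245 with an estimated correlation, 0.0245 with ranks and 0.0174 with fry). Without Sox2-negative pool 1 or Sox2-positive pool 1 the list's adjusted p was 0.0212 and 0.0455. Ttr, the main secreted protein of the choroid plexus, had a log2 difference of -1.05 (SE 0.38, limma adjusted p = 0.119; 0.00504 with the replicate block). Its values were 7.09 to 8.28 in Sox2-positive and 7.19 to 9.42 in Sox2-negative cells. Without Sox2-negative pool 1 its adjusted p was 0.00459.

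The remaining lists did not pass. Of 11 Wnt target genes, 1 was higher (2 higher and 1 lower adjusted over the list alone; median -0.04, mean 0.01, camera adjusted p = 0.978), and Rnf43 was 1.34-fold higher. Of 14 genes of the BMP and TGF-beta response, 0 passed, also adjusted over the list alone (median 0.09, camera adjusted p = 0.134). Id3 had a log2 difference of 0.35 (adjusted p = 0.0771; 0.039 without Sox2-positive pool 4). Of 13 p53 target genes, 1 was higher (2 adjusted over the list alone; median 0.07, camera adjusted p = 0.226), and Ccng1 was 1.61-fold higher. Of 12 efflux and detoxification genes, 2 were higher (3 adjusted over the list alone; median 0.05, camera adjusted p = 0.0627; adjusted p = 0.245 with an estimated correlation and 0.00391 with fry). Aldh1a1 was 1.75-fold higher. Abcc4 was 1.24-fold higher, a call that ended without Sox2-positive pool 2, 3 or 4 or Sox2-negative pool 1, 3 or 4 (0.0578 to 0.106). Of 15 ribosomal protein genes, 0 passed, also adjusted over the list alone (median -0.13, camera adjusted p = 0.053; adjusted p = 0.549 with an estimated correlation). The largest difference was that of Rps9, -0.23, whose other probe set differed by -0.06. The ribosomal list passed with quantile normalization (0.0108), with ranks (0.0168) and without Sox2-positive pool 3 or Sox2-negative pool 1 or 4 (0.00923 to 0.0304).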

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

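All tests of explanations in this part were chosen after the results were seen, and some replaced a first version whose value had been seen. Of 230 group values checked, those of 85 genes and 30 lists in each group, 23 had 1 array far from the other 3, where chance gives about 5%. Sox2-positive pool 3 stood high for Ptch1 (7.11), Olig2 (9.85), Ttr (8.28), Nr4a1 (7.87), Pfkp (6.82) and Fdps (7.75), and for the mean log2 value of the neural stem and radial glia list (7.67) and the oxidative phosphorylation list (7.49). Sox2-positive pool 2 stood low for Cacna2d1 (6.83) and Zic2 (8.24), and pool 1 stood low for Rps9 (7.43).

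Sox2-negative pool 3 stood high for Prdm8 (10.1), Cntn1 (7.80) and the neuronal differentiation list (7.81). Sox2-negative pool 2, which had the lowest array weight (0.51), stood high for Rps9 (8.10) and the DNA replication list (7.28). It stood low for Nr4a1 (5.996), the endothelial list (5.41) and the Purkinje cell and inhibitory interneuron list (5.50). Sox2-negative pool 4 stood low for Abcc4 (5.58) and Pfkp (6.23). Sox2-negative pool 1 stood low for the ependymal and choroid plexus list (5.90) and high for the Notch list (6.45).

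Among the 17824 probe sets outside the comparison, unnamed here or shared by several genes, 34 differed in limma, 29 higher and 5 lower in Sox2-positive cells. At an unadjusted p under 0.05, 1886 differed.

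With the arrays taken as unpaired, the real split gave the largest counts of genes (exact permutation p = 0.0286, the smallest this test can give). The other splits mix the fractions, so the real difference adds to the spread within their groups and lowers their counts. Of the 35 splits of the 8 arrays into 4 and 4, only 1, the real one, gave as many genes that differ (1879, highest of the others 1), genes higher (1321, highest 1), genes lower (558, highest 1) or genes at least 2-fold apart (377, highest 1). Only 8 splits part all 4 pairs of equal numbers, and the highest count of the other splits among them was 0 genes. These are too few for a share under 5%, as the real split alone is 0.125 of them. For gene lists with the preset correlation, 1 split, again the real one, gave 16, and the highest of the others gave 14, a split that parts all pairs. That split holds 3 arrays of one fraction and 1 of the other on either side, as do 16 in all (7 to 14 lists), and so keeps part of the real difference. The 18 splits with 2 arrays of each fraction on either side gave 0 to 8 lists (median 2). With an estimated correlation the real split gave 2 lists and the others gave 0.

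The first pattern was the lopsided size of the differences, with 81 genes higher and 0 lower by at least 4-fold. Unlike value distributions of the arrays were tested by quantile normalization, which left 13.9 genes at least 2-fold higher for each 1 lower. RMA had already brought the arrays to a common distribution (medians 5.83 to 5.88), so this step could only act on what RMA had left. Such remaining differences did not by themselves make the 2-fold counts lopsided. The 4-fold counts were not taken after this step, so it does not decide the pattern itself. Sox2-negative cells giving at least 50% of the RNA of the Sox2-positive fraction would keep every gene above that share of its Sox2-negative level. No called gene should then lie below it, but 19 were lower by at least 2-fold. Of these, only 2, Chrna3 and Cntn2, had a 95% interval wholly below it, fewer than the 3 set as the bound. That bound was set after the results were seen, and the intervals were not adjusted for the number of genes. This carry-over thus cannot be told apart from a true difference in the genes that fell. A smaller carry-over stays open as well.

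The next pattern was the rise of oligodendrocyte progenitor genes. Mature oligodendrocytes as its source are argued against by the mature list. Its median lay 2.03 below that of the progenitor list on the log2 scale (bootstrap 95% interval of the difference over genes 0.49 to 2.77). The bootstrap intervals here resampled genes, which vary together, and leave out the spread between arrays. No interval over arrays was made for the difference between these lists. A fraction made up of non-tumour oligodendrocyte progenitors alone is argued against, unless granule neuron progenitor transcripts were carried over with Sox2-negative cells. Granule neuron progenitor genes kept a median of 57.4% of their Sox2-negative level (bootstrap interval over genes 51.6% to 62.3%). Over arrays, the interval of the list's mean level was 44.9% to 68.1%, from inverting the exact permutation test of unpaired arrays. Tumour cells expressing oligodendrocyte progenitor genes and a share of non-tumour progenitors both stay open, since no marker of tumour origin was tested. A lower share of granule-lineage cells stays open too, as the sort itself sets which other cells the fraction holds.

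The last pattern was that genes of G2 and mitosis did not fall in Sox2-positive cells. Had their transcripts come only with carried-over Sox2-negative cells, they would have fallen with the granule neuron progenitor genes, but their median lay 0.96 above (bootstrap interval over genes 0.80 to 1.09; exact permutation p of the difference between array scores 0.0286, the smallest possible with n = 4 each and no pairing). Within the 4 pairs of equal numbers the single differences ran from 0.79 to 1.14, higher in 4 of 4, with an exact p of 0.125, the smallest 4 pairs can give. Too few arrays to see a fall to 50% is argued against by the interval of the list's mean log2 difference, -0.059 to 0.41, from inverting the exact permutation test of unpaired arrays (exact p of the list's mean 0.143). The lowest and highest of the 4 pair differences were -0.013 and 0.41 (exact p 0.25), and 4 pairs are too few for such an interval. The share of dividing cells among the Sox2-positive cells was not measured.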

How the results depend on the processing

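The alternatives were set before the data were examined. Over 8 alternatives besides leaving out arrays, genes that differ ranged from 1360 to 2340, genes higher from 999 to 1572 and genes at least 2-fold apart from 356 to 424. The 1360, 999 and 424 came from testing all probe sets singly and count probe sets, not genes. With genes as the unit, the fewest that differed were 1791, with median centring. No result changed direction past the test (0 reversed). Genes lower in Sox2-positive cells moved from 558 to 847 with quantile normalization, and the cause was not tested. With all probe sets tested singly, 361 probe sets were lower. Leaving out 1 array gave 309 to 591 genes lower, and 1304 to 1835 that differ, with fewer samples in each fit; it was 309 without Sox2-positive pool 2, 361 without pool 4 and 357 without Sox2-negative pool 1. Lists shifted fell from 16 to 2 with an estimated correlation, which takes the correlation of a list's genes from the arrays, and numbered 11 with fry and 17 with ranks. With the replicate block, which follows the pairing by number, 2340 genes differed (1572 higher, 768 lower, 378 at least 2-fold) and 17 lists were shifted; 1847 of the 1879 genes remained, and among named genes and lists only Ttr, Tyms and the ependymal list changed their call. Of 75 named genes past the test, 61 stayed past it in every alternative that tested them. Dim signal limits the folds of 19 of 85 named genes, among them Sox2 (4.30 in Sox2-negative cells), Serpina3n, Gad1 and Id3, with a group mean below the upper quartile of receptor genes (5.80).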

Other observations

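All tests in this part were chosen after the results were seen. Genes were grouped by the letters that open their symbols, and 259 such families of at least 10 members were tested for more calls than the other genes had, in each direction (Fisher's exact test, one-sided, 518 tests, Benjamini-Hochberg adjusted). The expected counts came from all 22180 genes, dim ones included. With the dimmer genes left out, 1817 of 11090 genes differed, 68.5% of them higher, so calls were more frequent among brighter genes. The family tests do not separate a family's own excess from that of brighter genes, as no family was compared with genes of like level. Of the 518 tests, 6 passed. Protocadherins with a number directly after Pcdh in the symbol, adhesion proteins of the cell surface, led with 9 of 12 higher in Sox2-positive cells where 0.715 were expected (adjusted p = 8.89e-07). The clustered Pcdhb genes did not pass, with 3 of 22 higher where 1.31 were expected (adjusted p = 1). Pcdh15 was 5.77-fold and Pcdh10 4.53-fold higher, both chosen after their values were seen. Of 30 sorting nexins, which act in membrane traffic, 10 were higher where 1.79 were expected (adjusted p = 0.00141).

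Solute carriers had 41 of 361 members higher where 21.5 were expected (adjusted p = 0.00697), and transmembrane proteins 30 of 226 where 13.5 were expected (adjusted p = 0.00564), both broad classes of unrelated function. Symbols opening with S and a digit, which are S100 calcium-binding proteins and sphingosine phosphate receptors, had 8 of 25 higher where 1.49 were expected (adjusted p = 0.00697). S100a1, chosen after its value was seen, was 9.10-fold higher. Its Sox2-negative mean (5.62) lay below the upper quartile of the receptor genes (5.80), so this fold may be understated. The 1 family with more members lower was that of small nucleolar RNA host genes, 4 of 15 where 0.377 were expected (adjusted p = 0.0374).

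The mean of 3 Y-linked genes followed the pool number in pools 2, 3 and 4. In pool 1 the Sox2-positive value was nearer that of Sox2-negative pool 4. Only in pool 3 did this mean lie above the median of the receptor genes (4.95), so most of its values were dim. In Sox2-positive and Sox2-negative cells it was 4.08 and 4.59 in pool 1, 4.73 and 4.74 in pool 2, 5.52 and 5.65 in pool 3, and 3.72 and 3.82 in pool 4, while Xist lay between 9.44 and 10.4 on every array.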
